A study of Rattus norvegicus with 12 samples.

How the data were processed

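The samples were 12 libraries of INS-1 832/3 cells, a rat insulinoma line used as a model of the pancreatic beta cell. Per the labels' protocols, RNA was isolated with a High Pure RNA kit and libraries were made with the QuantSeq 3prime mRNA FWD kit, which primes on the poly(A) tail and gives reads near the transcript end. Per the submitters' processing notes, FastQC, Bowtie2 and SAMtools were used, and no version was named. The read counter, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene, not normalized, with 1 column per library, and the series text states that this table was corrected after its first release. It held 31368 gene names, of which 24611 had at least 1 count. The library totals of deposited counts ran from 4828003 to 6681455.

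Gene names were used as the table gives them. Of these names, 20819 were found in the RefSeq gene table of the GRCr8 assembly, which served for names alone, and no coordinates are given because the build of the counts is not named. Placeholder names of the form LOC plus digits made up 11290 of the names. Genes with near-identical copies, such as the ribosomal protein genes with their pseudogenes, are uncertain because the handling of reads that fit several places is not stated.

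The libraries were grouped by their titles into untreated control, urolithin B (50 uM for 12 h), IAPP (2 uM for 24 h) and urolithin B followed by IAPP, with 3 biological replicates each. Whether these were separate cultures is not stated, so p-values measure the spread between these libraries, which may be technical. The labels do not state whether cells given urolithin B alone were kept for a further 24 h, nor from which species the IAPP sequence was taken. The counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr on the group, 1 fit of all 12 libraries and Benjamini-Hochberg adjustment at 0.05. The filter kept 16814 genes. Fold changes are on the log2 scale, ± is the standard error (SE) for a fold change and the standard deviation (SD) for CPM, counts scaled to the library total times its TMM factor (to the library total alone in the stricter filter), and n = 3 libraries per group. Tested were 6 contrasts: 5 pairwise ones and the interaction, the difference between the IAPP effects with and without urolithin B. IAPP against urolithin B, which differ in both treatments, was not tested. Before the data were examined, 30 gene lists were fixed. The 29 lists with at least 3 tested genes were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the correlation estimated from the data.

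The genes to be named were set by a rule fixed with the lists. Ins1, Ins2, Iapp, Ddit3, Hspa5, Txnip, Cyp1a1 and Nqo1 were always named where tested. Among called genes with at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups, the 12 largest rises and 12 largest falls were taken in IAPP against control, urolithin B against control and urolithin B + IAPP against IAPP, and 5 of each elsewhere, placeholder names skipped. Where a comparison called no gene, the 5 with the smallest p were taken. For each list described, up to 4 members with the smallest p were taken. Iapp was listed at 0 counts in all 12 libraries, and Cyp1a1 at 0 to 7 counts, so neither was tested.

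The replicate numbers paired the libraries. Deviations from the group means were correlated over genes between all 18 pairs of libraries with the same number, with r from 0.44 to 0.89, and the first principal component, with 68.6% of the variance, separated the 4 replicate 1 libraries from the other 8. The pairing rested on replicate 1. With those libraries left out, the same-number correlations ran from -0.06 to 0.02. With all 12 libraries in, 7 correlated best with their own number. A fit with the replicate number as a block is therefore given beside some results. These are results where it changes the call of a named gene or list, or the count of a comparison. Counts of called list members with the block are given for some lists only. The common biological coefficient of variation was 0.332 without the block and 0.104 with it. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts was 3.71 or more.

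The tests were run on simulated data with 200 changed genes of at least 5 CPM, drawn from the means, library sizes and dispersions of the real libraries. Apart from the changed genes, the groups of a replicate number shared 1 mean, and the dispersions were those of the blocked fit. The block was thus true by construction, and recovery with it may be overstated. In the simulated IAPP against control, over 16536 genes, 49% of 2-fold and 90% of 4-fold changes were recovered without the block, with 0 false calls. With the block 94% and 100% were recovered, with 13 false calls. In the simulated urolithin B against control, over 16516 genes, 44% of 2-fold and 89% of 4-fold changes were recovered without the block, and 94% and 100% with it, with 16 false calls. In the simulated urolithin B + IAPP against IAPP, over 16542 genes, the shares were 53% and 87% without the block and 89% and 100% with it, with 11 false calls. In the simulated interaction, over 16506 genes, the shares were 9% and 72% without the block and 77% and 99% with it, with 10 false calls. Alternatives were RLE size factors, library size alone, no filter, a stricter filter (at least 1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, fits of only the 2 groups compared, the replicate block and each library left out in turn. After the data had been seen, fits without the replicate 1 libraries, fits with a batch term for them, a reading of genes chosen in replicates 2 and 3 in replicate 1, the block with an estimated correlation and simulations of a combined treatment with no effect against control were added.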

Results

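Gene expression was measured by 3prime RNA sequencing in INS-1 832/3 cells, a rat insulinoma line that secretes insulin. The cells were left untreated, given urolithin B, a gut microbial metabolite of ellagitannins, challenged with islet amyloid polypeptide (IAPP), a beta-cell peptide that can form amyloid, or given urolithin B and then IAPP. Each of the 4 groups had 3 libraries. Total counts per library ran from 4893146 to 5422330 in control, 4927585 to 6583860 in urolithin B, 4828003 to 5266959 in IAPP and 5224896 to 6681455 in urolithin B + IAPP cells. The 4 replicate 1 libraries, 1 from each group, stood apart: 22139 to 22615 genes were detected in them against 19529 to 20201 in the other 8. Mitochondrial rRNA took 7.99% ± 1.01 (SD, n = 4) of their counts and 16.0% ± 2.97 (SD, n = 8) of the counts of the others. By group, this share was 11.6% ± 2.87 in control, 12.1% ± 2.84 in urolithin B, 15.1% ± 6.39 in IAPP and 14.3% ± 6.85 in urolithin B + IAPP cells (SD, n = 3).

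The first comparison asked what the peptide did on its own. IAPP raised genes of the p53 response. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 17.8 ± 2.48 CPM in control to 154 ± 18.4 CPM in IAPP cells (SD, n = 3), a log2 fold change of 3.11 ± 0.17 (edgeR adjusted p = 7.76e-06). Mdm2, which encodes the ubiquitin ligase that limits p53, rose by 1.83 ± 0.16 on the log2 scale, and Ccng1 went from 240 ± 24.3 to 1155 ± 267 CPM. Mafa, a transcription factor of mature beta cells, fell by 1.21 on the log2 scale, from 353 ± 40.2 to 152 ± 30.1 CPM, and Mnx1, another islet transcription factor, fell by 1.13. In total 92 genes rose and 50 fell among 16814 tested, and all 142 had no overlap between the 3 IAPP and the 3 control libraries. Over all tested genes 15.3% had no such overlap, where chance gives 10% for exchangeable libraries and the pairwise comparisons with 0 called genes gave 4.48% (urolithin B against control), 7.40% (urolithin B + IAPP against control) and 5.43% (urolithin B + IAPP against urolithin B). With the replicate block 636 genes rose and 680 fell, the 142 among them. With library size alone as the scaling, 24 rose and 31 fell, so that 43.6% of calls were rises against 64.8% with TMM. The count was 42 without control replicate 2, 43 without IAPP replicate 2 or IAPP replicate 3, 49 without control replicate 3 and 86 without control replicate 1. Replicates 2 and 3 alone gave 754 genes, while replicate 1, with 1 library per group, was too small for a test.

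The largest rises after IAPP were those of Tubb6, at 3.20 on the log2 scale, Cdkn1a, Plk2 (3.01), Fam212b (2.98), Tp53inp1 (2.90), Phlda3 (2.81), Lrrc25 (2.34), Ccng1 (2.27), Tap1 (2.26), Sulf2 (2.04), Unc5b (1.95) and Nqo1 (1.85). Nqo1, a quinone reductase, stood at 4.8 ± 0.47 CPM in control and 17.3 ± 1.80 CPM in IAPP cells. The largest falls were those of S100a4 (-3.16), Cyp4f1 (-3.07), Pabpn1l (-1.72), Gpr6 (-1.55), Rprml (-1.51), Tex21 (-1.5), Padi2 (-1.35), Gad1 (-1.30), Pde2a (-1.26), Mafa, Cdh4 (-1.15) and Mnx1. Their edgeR adjusted p-values lay between 7.76e-06 for Cdkn1a and 0.0355 for Padi2. The insulin genes did not pass the test, with log2 fold changes of 0.31 ± 0.33 for Ins1 and -0.39 ± 0.29 for Ins2. Ddit3, a marker of endoplasmic reticulum stress, had a change of -0.08 ± 0.29. Hspa5 (-0.57 ± 0.35) and Txnip (-0.59 ± 0.41) did not pass without the block, and with the block their edgeR adjusted p-values were 0.00295 and 0.0127.

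Of the 24 tested genes of the p53 and apoptosis list, 11 rose after IAPP, 0 fell and 13 did not pass (adjusted over the list alone, 14 rose). The median log2 fold change was 0.99, with camera adjusted p = 1.52e-21 and adjusted p = 0.00013 with an estimated correlation. Zmat3 rose by 1.26 ± 0.11 and Btg2, an antiproliferative gene, by 1.60 ± 0.14. Without the block this was the 1 list whose call held with an estimated correlation. Of 75 cytosolic ribosomal protein genes, 4 fell, 0 rose and 71 did not pass (adjusted over the list alone, 28 fell), and with the replicate block 49 fell. Rpl14 (-0.68 ± 0.13), Rpl35a (-0.71 ± 0.13), Rpl27a (-0.57 ± 0.11) and Rps9 (-0.56 ± 0.10) were those called. The list's median was -0.42, with camera adjusted p = 6.16e-31 but adjusted p = 0.116 with an estimated correlation. Its share of all counts was 2.25% ± 0.15 in control and 1.60% ± 0.16 in IAPP cells (SD, n = 3). Without the block no gene of the ribosome biogenesis list passed over all genes. Adjusted over the list alone 6 of 20 fell, and with the replicate block 10 fell over all genes. The list's median was -0.44 (camera adjusted p = 7.93e-09, adjusted p = 0.116 with an estimated correlation). In the cholesterol synthesis list Ebp fell by 0.95 on the log2 scale, and the other 21 tested genes did not pass (adjusted over the list alone, 1 fell). Its median was -0.41, with camera adjusted p = 2.00e-06, adjusted p = 0.353 with an estimated correlation and 0.0249 with an estimated correlation and the replicate block.

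Among 22 tested beta-cell identity genes, Mafa fell, Nkx6-1 rose by 0.71 ± 0.12 and 20 did not pass. Adjusted over the list alone 1 rose and 3 fell, and with the block 1 rose and 5 fell over all genes. Slc2a2, the glucose transporter of rodent beta cells, had a change of -0.77 ± 0.17 that missed the threshold without the block (edgeR adjusted p = 0.0589) and passed with it (1.13e-05). The list's median was -0.17, with camera adjusted p = 0.00200 and adjusted p = 0.353 with an estimated correlation. Further lists called lower by camera were heat shock (median -0.36), hypoxia (-0.40), glycolysis (-0.28), integrated stress response (-0.27), nuclear oxidative phosphorylation (-0.18) and proteasome (-0.16). Their adjusted p-values with an estimated correlation were 0.255, 0.0785, 0.0785, 0.479, 0.479 and 0.479 in that order. With the block 9, 6, 5, 10, 4 and 3 of their genes fell in the same order, and 1 hypoxia and 2 stress response genes rose. In the stress response list Ddit4 (1.82 ± 0.20) and Sesn2 (0.62 ± 0.11), both also induced by p53, rose against the median. Called higher were the aryl hydrocarbon receptor (median 0.76), interferon (0.39), NF-kB (0.32), and G2 and M phase (0.21) lists and 3 exocrine and ductal markers (1.10), with adjusted p = 0.0504, 0.116, 0.152, 0.479 and 0.116 with an estimated correlation. In that order their called members were Nqo1, Tap1, none, Kif20a (0.99 ± 0.16) and Krt7 (1.10 ± 0.22). Adjusted over the list alone 3, 2, 0, 1 and 2 genes rose. With the block, 4 aryl hydrocarbon receptor and 2 NF-kB genes rose over all genes. The endoplasmic reticulum chaperone list was called with the replicate block alone (camera adjusted p = 0.000743, median without the block -0.14), and not with the block and an estimated correlation (adjusted p = 0.190).

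**Figure D1:**
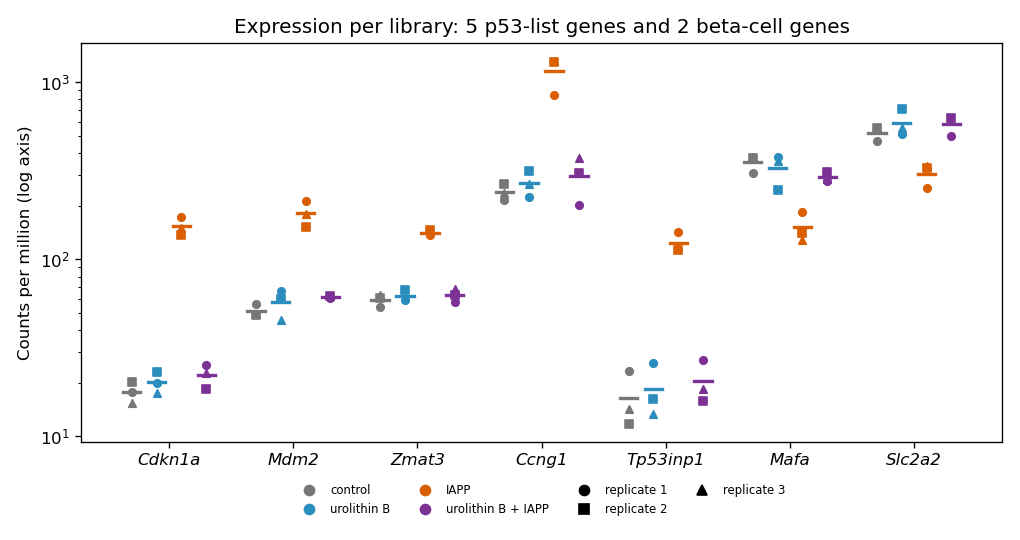
CPM on a log axis for 5 genes of the p53 list and 2 beta-cell genes in each of the 12 libraries, with symbols for replicate numbers, colours for the 4 groups and bars for group means. Cdkn1a averaged 154 CPM in IAPP cells and 17.8 to 22.2 CPM in the other groups.

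The second comparison asked what urolithin B did in unchallenged cells. No gene passed the edgeR test, with 151 of 16814 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Replicates 2 and 3 alone gave 0 genes as well. These 2 libraries differed more in urolithin B cells than in the other groups. Their chi-square per degree of freedom was 17.6, against 4.33 in control, 5.27 in IAPP and 3.71 in urolithin B + IAPP cells. Without urolithin B replicate 2 the count was 0 too. The 5 genes with the smallest p were not called: Wdyhv1 (0.59 ± 0.14), Dnai1 (0.50 ± 0.13), LOC100912622 (0.66 ± 0.18), Pmf1 (-0.38 ± 0.10) and Hivep1 (0.39 ± 0.11), each with edgeR adjusted p = 1.00. Cdkn1a stood at 20.2 CPM, and its change was 0.18 ± 0.17. Ins1 (0.50 ± 0.34), Ins2 (0.36 ± 0.29), Hspa5 (-0.10 ± 0.35), Txnip (-0.19 ± 0.40), Ddit3 (-0.04 ± 0.29) and Nqo1 (0.14 ± 0.19) did not pass. With the replicate block 1 gene rose, Gcg, the proglucagon gene, at 0.95 ± 0.13 (adjusted p = 0.00103). Camera called 5 lists: G2 and M phase (median -0.10), ribosomal proteins (-0.05), proteasome (-0.11), secretory granule (0.06) and 3 exocrine and ductal markers (0.44). With an estimated correlation the adjusted p was 0.916 for the first 4 and 0.784 for the last, and with the block none of the 29 lists was called (camera adjusted p = 0.0550, 0.0550, 0.0764, 0.0550 and 0.148 for these 5).

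The third comparison, the centre of the design, asked what urolithin B changed in challenged cells. Genes raised by IAPP were lower when urolithin B had been given first. Cdkn1a was at 22.2 ± 3.44 CPM in urolithin B + IAPP cells against 154 ± 18.4 CPM in IAPP cells, a log2 fold change of -2.80 ± 0.16 (edgeR adjusted p = 2.06e-05), and Ccng1 was at 296 ± 86.2 against 1155 ± 267 CPM. Mafa was higher by 0.93 ± 0.18 on the log2 scale (edgeR adjusted p just under the threshold of 0.05) and Slc2a2 by 0.93 ± 0.17. In total 26 genes were higher and 71 lower. With the replicate block 422 were higher and 459 lower, the 97 among them, and with library size alone 7 were higher and 11 lower, which puts 38.9% of calls on the higher side against 26.8% with TMM. The count was 25 without urolithin B + IAPP replicate 2 or 3, 28 and 30 without IAPP replicate 3 and 2, 48 without replicate 1 of either group, and 51 and 57 without control replicate 3 and 2. Replicates 2 and 3 alone gave 418 genes.

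The largest falls were Fam212b (-3.31), Cdkn1a, Tp53inp1 (-2.59), Plk2 (-2.34), Tubb6 (-2.22), Phlda3 (-2.20), Unc5b (-2.0), Ccng1 (-1.96), Ddit4 (-1.79), Zfp862 (-1.74), Pvt1 (-1.72) and Sulf2 (-1.66). The largest rises were Pabpn1l (1.80), Padi2 (1.44), Gpr6 (1.34), Cdh4 (1.31), Stk32c (1.05), Mnx1 (1.05), Rab3b (1.03), Mafa, Slc2a2, Slc25a53 (0.88), Dcx (0.85) and Cdh23 (0.79). Nqo1 fell by 1.20 on the log2 scale. Ins1 (0.26 ± 0.33), Ddit3 (-0.01 ± 0.29) and Txnip (0.14 ± 0.41) did not pass. Ins2 (0.58 ± 0.29) and Hspa5 (0.51 ± 0.35) passed with the block alone, with edgeR adjusted p-values of 0.00672 and 0.0143.

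Of the 24 genes of the p53 and apoptosis list, 10 fell, 0 rose and 14 did not pass (adjusted over the list alone, 13 fell). Mdm2 fell by 1.57, Aen by 1.22 and Zmat3 by 1.17 on the log2 scale. The median was -0.72, with camera adjusted p = 3.09e-20 and adjusted p = 0.000156 with an estimated correlation. None of the 75 ribosomal protein genes passed over all genes or adjusted over the list alone, all 75 fold changes were positive, and with the replicate block 17 rose. The list's median was 0.30 (camera adjusted p = 1.56e-19, adjusted p = 0.349 with an estimated correlation). In the beta-cell identity list Mafa and Slc2a2 rose, Nkx6-1 fell by 0.71 and 19 genes did not pass (adjusted over the list alone, 3 rose and 1 fell), with a median of 0.24 (camera adjusted p = 0.000103, adjusted p = 0.349 with an estimated correlation). Camera also called cholesterol synthesis (median 0.42), endoplasmic reticulum chaperones (0.31), ribosome biogenesis (0.29), heat shock (0.23), nuclear oxidative phosphorylation (0.22), proteasome (0.14), glycolysis (0.13) and fatty acid synthesis (0.13) higher. Their adjusted p-values with an estimated correlation were 0.349, 0.587, 0.349, 0.483, 0.483, 0.620, 0.349 and 0.483, and for cholesterol synthesis 0.0156 with the block as well. The aryl hydrocarbon receptor (-0.78), G2 and M phase (-0.23), interferon (-0.22) and NRF2 (-0.08) lists were called lower, with adjusted p = 0.0566, 0.483, 0.349 and 0.326 with an estimated correlation. With the block the interferon and NRF2 calls ended (camera adjusted p = 0.239 and 0.0587), and the secretory granule and integrated stress response lists were called higher (0.0368 and 0.0303), but not with the block and an estimated correlation (adjusted p = 0.350 and 0.324).

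All 142 genes called in IAPP against control had a change of the opposite sign in urolithin B + IAPP against IAPP. Both comparisons use the same IAPP libraries. In 100 simulations with no urolithin B effect in challenged cells, the share was 64.4% at the median and at most 71.3%. These simulations drew genes independently, with the dispersions of the blocked fit and the block true by construction. Genes that move together in the real libraries could widen the simulated ranges, so their limits may be too narrow. Of the 92 raised genes, 54 were called lower with urolithin B, and of the 50 lowered genes 19 were called higher. Independent lists would share 0.388 and 0.0773 genes, but these lists share the IAPP libraries. In the simulations, which share them too, the largest count of genes called in both with opposite signs was 0, against 73. A comparison simulated without an effect should call almost no gene, so this 0 says little about the overlap. The covariance of the 2 sets of fold changes over genes was -0.108 against -0.0421 in the simulations, a difference of -0.0664. In urolithin B + IAPP cells the median gene of the 142 stood at 17.5% of its IAPP change, and 111 of them (78.2%) lay on the IAPP side of control. These genes were chosen against the same control libraries, and in 100 simulations in which the combined treatment had no effect the medians of these values were 5.06% (at most 8.34%) and 64.0% (at most 73.3%). In cells given urolithin B alone they were 7.48% and 74.6%. That 74.6% lay above the simulated maximum of 73.3%, although urolithin B alone called 0 genes. These simulations also drew genes independently with the block true by construction, so their maxima may be too low. They do not decide whether the 142 genes kept a remainder of the IAPP change. Against urolithin B alone, 64.8% of the 142 had the sign of the IAPP change with the block, against 53.7% of all genes. The slope was 0.10. This contrast shares no library with IAPP against control. The scaling and spread used to choose the genes came from all 12 libraries, however, so the choice was not fully independent of this reading. To choose and read genes in separate libraries, 775 genes were called in replicates 2 and 3 with the block. In replicate 1, with 1 library per group and so no test, 88.5% of them had moved back. Over all genes the share in replicate 1 was 73.1%, but there both changes were read from the same IAPP library. It is therefore no baseline for the 88.5%.

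**Figure D2:**
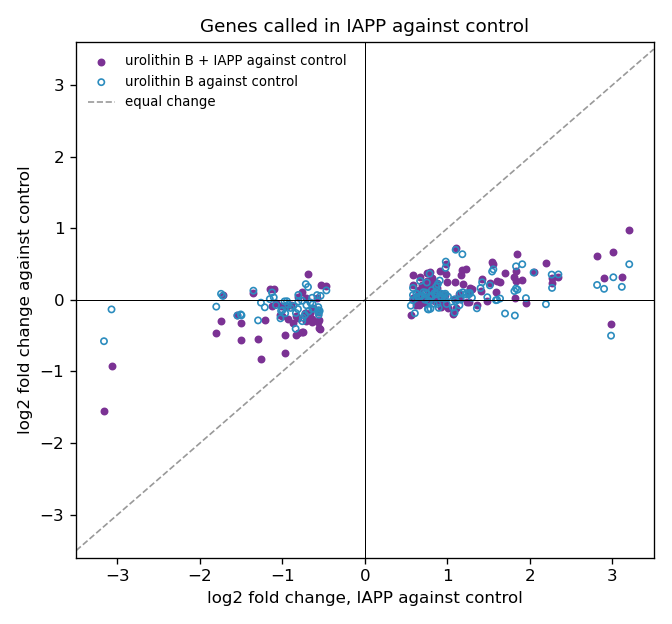
Log2 fold changes against control of the 142 genes called in IAPP against control, with the change after IAPP on the x axis and the change after urolithin B + IAPP (filled) or urolithin B alone (open) on the y axis. All 142 filled points lie nearer to 0 than the dashed line of equal change.

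The remaining pairwise comparisons set the combined treatment against control and against urolithin B alone. Neither called a gene with edgeR. Against control 411 genes and against urolithin B 281 genes had an unadjusted p under 0.05. DESeq2 called 5 and 0, and limma-voom 0 in both. The smallest p-values against control belonged to Car8 (0.63 ± 0.11), Clpb (-0.47 ± 0.10), Jmy (-0.60 ± 0.14), LOC363324 (-1.0 ± 0.23) and Fbxo4 (0.89 ± 0.22), and against urolithin B to Zdhhc4 (0.46 ± 0.10), Hopx (1.08 ± 0.25), Plgrkt (0.55 ± 0.13), Med21 (0.72 ± 0.17) and Wdyhv1 (-0.54 ± 0.14), none of them called. Nqo1 had fold changes of 0.65 ± 0.19 and 0.51 ± 0.19 and was not called. With the replicate block 7 genes were higher and 5 lower than control, and 2 were lower than in urolithin B cells. Gcg (1.13 ± 0.13) and Car8 (0.63 ± 0.10) were among the former, and Plcxd3 and Ambp were lower in both comparisons. Against control the p53 list had a median of 0.23 with 0 of 24 genes called (adjusted over the list alone, 0), camera adjusted p = 0.00386 and adjusted p = 0.0801 with an estimated correlation. The other 10 lists called against control had medians of 0.18 for endoplasmic reticulum chaperones, -0.15 for glycolysis, -0.13 for hypoxia, -0.12 for ribosomal proteins, -0.15 for ribosome biogenesis, -0.16 for heat shock, 0.19 for NF-kB, 0.19 for S phase, 0.11 for fatty acid oxidation and 0.66 for exocrine and ductal markers. In that order, their adjusted p with an estimated correlation was 0.914, 0.308, 0.0801, 0.607, 0.464, 0.607, 0.0801, 0.464, 0.198 and 0.198. With the block the glycolysis, fatty acid oxidation and exocrine calls ended (camera adjusted p = 0.0711, 0.104 and 0.0729), and 13 mitochondrial genome transcripts were called (0.00304, but 0.610 with the block and an estimated correlation). Against urolithin B the ribosomal protein list (-0.09) and the S phase list (0.21) were called, with adjusted p = 0.842 and 0.791 with an estimated correlation. The block added endoplasmic reticulum chaperones, nuclear oxidative phosphorylation and mitochondrial genome transcripts (camera adjusted p = 0.0224, 0.0392 and 0.00191), none of which was called with the block and an estimated correlation (adjusted p = 0.484 for each). Scaling by library size alone moved the median of all genes against control from 0.02 to -0.09, and that of the ribosomal protein list from -0.12 to -0.23.

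Over the 16814 genes, the IAPP effect with and without urolithin B had r = 0.14 (Spearman rho 0.15, covariance 0.0180), and the urolithin B effect with and without IAPP had r = -0.02 (rho -0.03, covariance -0.00181). These are correlations across genes, which are not independent replicates. Leaving out 1 library moved the first from -0.20, without the urolithin B + IAPP replicate 1 library, to 0.27, without the control replicate 1 library, and it was -0.19 without the IAPP replicate 1 library. The second ran from -0.19 to 0.13.

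The interaction tested whether the IAPP effect differed between cells with and without urolithin B. It passed for 5 genes, all with a lower IAPP effect after urolithin B: Cdkn1a (-2.98 ± 0.23, edgeR adjusted p = 0.000482), Mdm2 (-1.72 ± 0.22), Zmat3 (-1.25 ± 0.15), Il15 (-1.22 ± 0.17) and Aen (-1.20 ± 0.17). With the replicate block 103 genes had a positive and 171 a negative interaction, the 5 among them. With library size alone as the scaling 1 gene had a positive and 4 a negative interaction, and of the 5 named Cdkn1a alone still passed. Nqo1 (-1.34 ± 0.26) passed with the block alone (adjusted p = 0.0238). Without any 1 library the count was 1 or 2, and replicates 2 and 3 alone gave 107 genes. With the block the interferon list was no longer called (camera adjusted p = 0.245), while the stress response, glycolysis and hypoxia lists were (0.0363, 0.0472 and 0.0472), though not with the block and an estimated correlation (adjusted p = 0.344 for each). The cholesterol synthesis list (median 0.51) was called without the block (camera adjusted p = 2.17e-06), and with an estimated correlation its adjusted p was 0.411 without the block and 0.0223 with it. Of the p53 list 4 genes passed and 20 did not (adjusted over the list alone, 12 passed), with a median of -1.11, camera adjusted p = 7.56e-19 and adjusted p = 0.000204 with an estimated correlation.

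**Figure D3:**
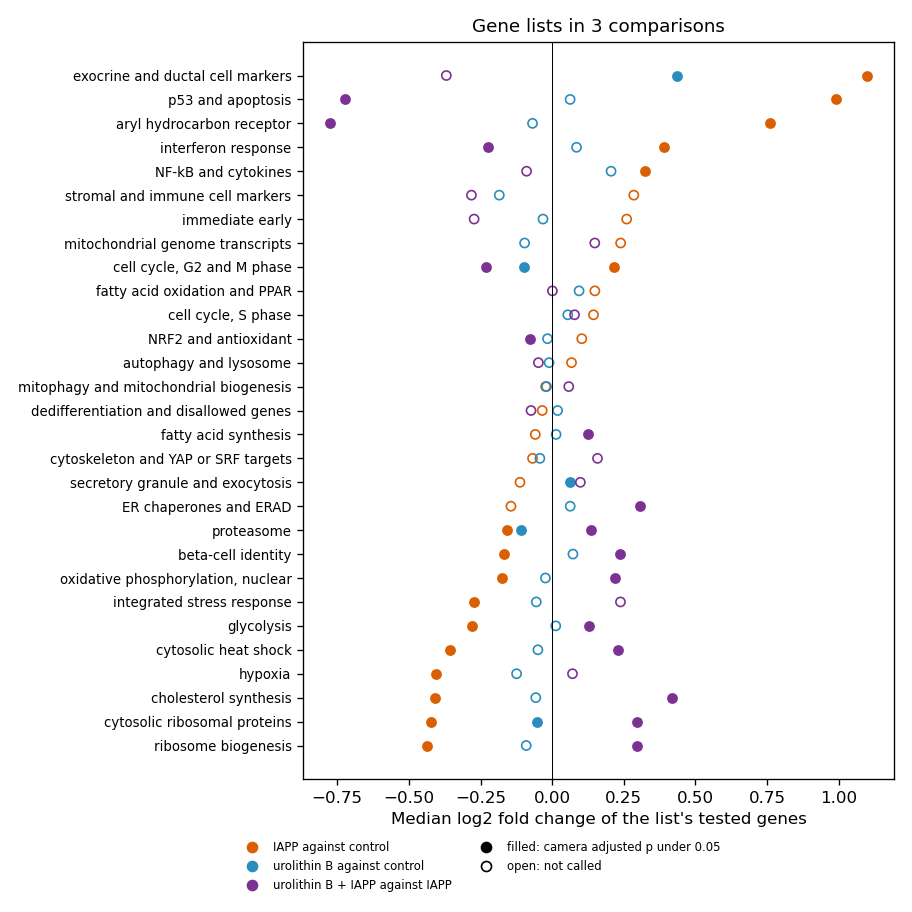
Median log2 fold change of the tested genes of each of 29 gene lists in 3 comparisons, with filled points for lists called by camera at the preset correlation. With an estimated correlation 1 list was called in IAPP against control, 0 in urolithin B against control and 1 in urolithin B + IAPP against IAPP. The p53 list had medians of 0.99 after IAPP, 0.06 after urolithin B and -0.72 in urolithin B + IAPP against IAPP.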

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

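The tests of exchanged libraries, of absent peptide, of sequencing depth, of scaling, of joint movement of genes, of assignments within replicate numbers and of the block with an estimated correlation were chosen after the result was seen. The difference between the IAPP effects with and without urolithin B passed its own test for 5 genes, with interaction log2 fold changes of -2.98 for Cdkn1a, -1.72 for Mdm2, -1.25 for Zmat3, -1.22 for Il15 and -1.20 for Aen. Among gene lists, the median interaction was -1.11 for p53 and apoptosis, -1.07 for exocrine and ductal markers, -0.58 for the aryl hydrocarbon receptor and -0.27 for interferon. It was 0.51 for cholesterol synthesis, 0.36 for ribosomal proteins, 0.31 for ribosome biogenesis, 0.29 for endoplasmic reticulum chaperones, 0.24 for nuclear oxidative phosphorylation, 0.24 for heat shock, 0.22 for beta-cell identity and 0.21 for proteasome. Of these 12 lists the p53 list alone held with an estimated correlation and no block, and cholesterol synthesis held as well with the block (adjusted p = 0.0223). For the other 11, from exocrine markers to proteasome in the order given, the adjusted p with an estimated correlation and no block was 0.281, 0.165, 0.403, 0.411, 0.403, 0.403, 0.761, 0.513, 0.510, 0.513 and 0.596.

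In 100 assignments of the 12 libraries to the 4 groups, the real one included, 6 gave 5 or more interaction genes, so chance could not be excluded at a share of 0.05 over assignments that ignore the replicate numbers. The highest other count was 4968. In 4 of the 5 others all replicate 1 libraries fell on one side of the contrast, which points to the structure of the samples. Among 100 assignments that kept 1 library of each replicate number in each group, 4 gave as many genes, with 40 as the highest other. With the block the real count of 274 was reached by 2 of 100, with 769 as the highest other. Both shares are under 0.05, but these assignments exchanged all 4 group labels, so the IAPP effect itself could set the real one apart. They were also chosen after the result was seen and follow the pairing, which rests on replicate 1. Chance is therefore not excluded for the interaction. For each pairwise comparison the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 142 and 0 genes for IAPP against control (1 of 10 splits as large), 97 and 0 for urolithin B + IAPP against IAPP (1 of 10), and 0 and 0 for urolithin B against control, urolithin B + IAPP against control and urolithin B + IAPP against urolithin B (10 of 10 in each). Among the 4 splits that parted all 3 pairs, the blocked fit gave 1316 genes for the real and 0 for the other 3 in IAPP against control, 881 and 0 in urolithin B + IAPP against IAPP, 1 and 0 in urolithin B against control and 12 and 0 in urolithin B + IAPP against control. In urolithin B + IAPP against urolithin B, where the real split gave 2, another gave 14.

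The p53 list stood high in the 3 IAPP libraries and in no other library. The lowest IAPP library lay 0.657 above the highest other library in median log2 CPM relative to its replicate number (SD among the other 9, 0.0844), but this gap is the pattern itself and an exchange of whole groups would leave it, so exchanged labels cannot be told apart from a response to IAPP. The mitochondrial rRNA share, put in as a covariate beside the replicate block, left 11 of the 11 called p53 list genes past the threshold, with their median fold at 1.83 before and 2.04 after. With no active peptide in the urolithin B + IAPP cultures the 142 IAPP genes would show no shared shift against urolithin B alone, but limma's model-based fry, which tests whether a set moves one way and was used because an exact permutation of 3 against 3 libraries cannot pass the threshold, gave p = 0.000433 with the block and 0.00171 with the mitochondrial covariate as well, at a slope of 0.10 of the IAPP change. The 142 genes were called in 1 fit of all 12 libraries, so their choice was not fully independent of this remaining shift. A weaker dose of active peptide in those cultures may leave such a remainder and stays open. A change of the peptide by direct contact with urolithin B and a response of the cells to urolithin B may leave one too. Both stay open as well. The labels do not state whether urolithin B cells were kept for a further 24 h, so a difference in culture time stays open too.

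The 4 replicate 1 libraries held more detected genes than the other 8. The replicate 1 totals averaged 5.15e+06 counts against 5.62e+06 in the other 8, so they were not deeper, which argues against depth. After every library was thinned to 4828003 counts, the smallest replicate 1 library still exceeded the largest other by 2265 genes, against an SD of 180 among the 8. Since depth did not favour replicate 1, this thinning adds little. With 39 mitochondrial genes removed and the rest thinned to 3589706 counts the gap was 2122 genes, against an SD of 108, which argues against the mitochondrial share. A difference in library preparation or day stays open, since no label names one, and no biological explanation was tested because the design gives none.

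Ribosomal protein genes stood lower after IAPP, with 75, 74 and 70 of 75 genes lower than control in replicates 1, 2 and 3. A scaling factor moves every gene of a library alike, and the list's median lay apart from that of all genes, at a difference of -0.468 (SD over the 3 replicates 0.133), which argues against scaling as the whole cause. With the mitochondrial rRNA share as a covariate beside the block the difference was -0.463, which argues against that share. Joint movement of these genes by chance cannot be told apart from a response to IAPP, because the smaller of the adjusted p-values with an estimated correlation, with and without the block, was 0.0906. Reads shared with pseudogene copies were not tested.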

How the results depend on the processing

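The replicate 1 fits, the batch term, the reading in separate libraries and the block with an estimated correlation were chosen after the data had been seen. Counts for IAPP against control, urolithin B + IAPP against IAPP and the interaction (142, 97 and 5) became 1316, 881 and 274 with the replicate block, 1331, 903 and 273 with a batch term for replicate 1, 754, 418 and 107 without the replicate 1 libraries, 775, 420 and 116 without them and with the block, and 482, 288 and 101 with DESeq2. The first 2 were 55 and 18 with library size alone and 90 and 23 with only the groups compared. The interaction was 3 without a filter, 8 with the stricter filter, 8 with limma-voom and 5 with library size alone, of which 1, Cdkn1a, was among the 5 with TMM. The other 4 with TMM kept their sign with edgeR adjusted p from 0.209 (Zmat3) to 1.00 (Il15). Urolithin B against control, urolithin B + IAPP against control and urolithin B + IAPP against urolithin B (0 each) gave 1, 12 and 2 with the block and 1, 11 and 1 with the batch term, and urolithin B + IAPP against control gave 5 with DESeq2 and 4 without replicate 1 and with the block. The block and the batch term take up the replicate 1 difference. For the other settings the cause was not tested.

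Leaving out 1 library at a time gave 42 (control replicate 2) to 154 genes for IAPP against control, with 43 without IAPP replicate 2 or 3, 49 without control replicate 3 and 86 without control replicate 1. It gave 25 (urolithin B + IAPP replicate 2 or 3) to 99 for urolithin B + IAPP against IAPP, with 28 and 30 without IAPP replicate 3 and 2, 48 without replicate 1 of either group and 51 and 57 without control replicate 3 and 2. It gave 1 to 2 for the interaction and 0 for the other 3 comparisons. A group left with 2 libraries has less power by construction.

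The share moved back was 97.9% with the block, 97.7% with the batch term, 98.5% without replicate 1, 98.3% without it and with the block, 88.5% in separate libraries and 100% with any library left out. The correlation of the IAPP effects ran from -0.20 to 0.27 with a library left out and was 0.11 with the block. That of the urolithin B effects was -0.04 with the block, turned to 0.000153 with library size alone, 0.00383 without a filter and 0.0320 with limma-voom, and ran from -0.19 to 0.13 with a library left out. The cause was not tested.

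Of 767 gene results 74 were called, and a call could be lost from these alone. Over the 767 and their alternatives, 16524 values kept direction and side of the threshold (in 217 of them the sign differed with neither value past it), 425 lost the call, 459 gained one and 1 reversed: Col1a1 in IAPP against control, -1.40 without replicate 1 and with the block. Of the 425 losses, 315 came with 1 library left out. Over 61 called lists 1025 values kept the call, 296 lost it and 9 turned the direction of the test. None of the 9 passed in the turned direction (camera adjusted p from 0.173 to 0.998), and in some the median kept its sign. In urolithin B against control these were the secretory granule (median 0.0146 without control replicate 1), proteasome (-0.00326 without urolithin B replicate 1) and ribosomal protein lists (0.0582 without urolithin B replicate 1, 0.0299 without replicate 1 and 0.0291 without it and with the block). The others were proteasome in urolithin B + IAPP against IAPP (-0.0300 without IAPP replicate 1), endoplasmic reticulum chaperones in urolithin B + IAPP against control (0.0102 without control replicate 1) and in the interaction (0.0356 without IAPP replicate 1), and ribosomal proteins in urolithin B + IAPP against urolithin B (0.0447 without urolithin B replicate 2). Over the left-out libraries these medians ran, in that order, from 0.0146 to 0.106, -0.168 to 0.0107, -0.164 to 0.0582, -0.0300 to 0.234, 0.0102 to 0.376, 0.0356 to 0.490 and -0.156 to 0.0447. Among the genes and lists given for a comparison in the text, the block changed no call other than those stated there. The cause was not tested. With 4828003 to 6681455 counts per library and this spread, 44% of simulated 2-fold changes in urolithin B against control were recovered without the block and 94% with it, where the real fit called 1 gene. The simulation made the block true by construction, so the 94% may overstate what the real fit could recover. Changes under 2-fold, and those of genes under 5 CPM, were not simulated and stay open.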

Other observations

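The test with the block and an estimated correlation was chosen after the data had been seen. With the replicate block, Gcg, which encodes proglucagon and marks alpha cells, was higher in both groups that received urolithin B. It stood at 64.8 CPM in control, 126 in urolithin B, 91.5 in IAPP and 141 in urolithin B + IAPP cells, and within each replicate number the urolithin B library lay above control: 37.1 against 18.5 CPM in replicate 1, 211 against 98.5 in replicate 2 and 129 against 77.4 in replicate 3. The blocked fit also put Gcg higher in IAPP than in control cells (0.50 ± 0.13, edgeR adjusted p = 0.0139), and no comparison of Gcg passed without the block. Ghrl, the other tested gene of 10 islet endocrine markers, had a change of -0.21 ± 0.32 in urolithin B against control.

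Some transcripts, singled out after their values were seen, were lower than control in both groups given IAPP with the block. Plcxd3 stood at 122 CPM in control, 69.0 in IAPP and 70.0 in urolithin B + IAPP cells, and Ambp at 106, 53.6 and 63.1 CPM. Cacna1a, a voltage-gated calcium channel gene, was at 486, 346 and 329 CPM. With the block all 3 were lower in urolithin B + IAPP cells than in control (adjusted p = 0.00114 for Plcxd3, 0.00376 for Ambp and 0.0238 for Cacna1a), and in IAPP cells than in control (5.58e-05, 2.92e-06 and 0.00348). Without the block Ambp alone passed in IAPP against control (edgeR adjusted p = 0.0388, against 0.455 for Plcxd3 and 0.776 for Cacna1a), and none of the 3 in urolithin B + IAPP against control (1.00 for each). The mitochondrial tRNA genes Trnq and Trne were higher in urolithin B + IAPP cells than in control with the block, by 1.18 ± 0.14 and 1.01 ± 0.17, and the 13 mitochondrial genome transcripts had a median of 0.45 (camera adjusted p = 0.00304 with the block, adjusted p = 0.610 with the block and an estimated correlation). The mitochondrial rRNA share differed between replicate 1 and the others by more than between groups. Within replicates 2 and 3, however, it was 16.2% and 20.9% in IAPP and 19.4% and 17.1% in urolithin B + IAPP cells. In the same replicates it was 13.1% and 13.5% in control and 13.8% and 13.7% in urolithin B cells. Replicate 1 did not show this, with 8.27% in IAPP and 6.52% in urolithin B + IAPP against 8.33% in control and 8.83% in urolithin B cells.

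Iapp was listed at 0 counts in all 12 libraries, although the line derives from beta cells. The table therefore gives no level of the endogenous gene to set beside the added peptide.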
